A study of Mus musculus with 384 samples.

How the data were processed

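Single-cell RNA sequencing of cells from the spinal cords of mice carrying a knockout of Optn (optineurin, an autophagy receptor that also acts in TNF and NF-kB signalling) was used here. Per the labels' protocols, spinal cords were digested with Accutase, myelin was spun out, antibodies to CD45, CD11b and CX3CR1 marked the cells, and individual cells were sorted into plates and prepared by SmartSeq2, a full-length cDNA method without molecular identifiers. The series title names the sorted cells as microglia. The labels list 384 cells on 4 plates of 96, and 326 of them have a column in the table; the other 58 were not analysed here. All cells carry the same genotype label and no cells without the knockout were analysed here, so no effect of the knockout was measured. The replicate number in the description label assigns plates 1 and 2 to replicate 1 and plates 3 and 4 to replicate 2. Whether the replicates are separate mice is not stated in the labels, so the spread between these 2 samples may be technical. The p-values rest on this spread as limma pools it over genes, and not on each gene's own spread alone. Cells were not counted as replicates, and n is 2 except in the alternative that fits averages per plate. There the spread is that between plates, which are technical.

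The authors deposited TPM values (transcript abundance scaled to a fixed total per cell) for 23420 genes in each cell. Per the submitters' processing notes, RSEM and the mm10 mouse genome build were used; the versions, the aligner and the annotation are not given in the sources used here. The values of each cell sum to 1000000, so the table keeps no sequencing depth, and the number of genes with TPM above 0 in a cell stood in for it. TPM expresses each gene as a share of the cell's total, so a few abundant genes lower all others. A value of 0 can be a failed estimate at low depth: 9283 genes (39.6%) are at 0 in every cell, and genes that every cell uses are at 0 in some cells. Such genes are therefore described as listed at 0. Intervals on shares of cells are exact 95% binomial intervals, and a share of 0 is given with the limit that a count of 0 allows (3 cells of the total). Both cover counting error only, and limit cells with a value above 0, not cells that express the gene.

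A cell was kept with at least 500 genes above 0 and less than 20% of its TPM on mitochondrially encoded genes. The table holds 0 mitochondrially encoded genes, so the second filter had no effect, and 0 cells were removed. No doublet caller was run. Clusters were made in scanpy 1.11.5 (Python 3.11.15) from log2(TPM + 1) of the 2000 most variable genes, with plate means removed, 20 principal components, 15 neighbours and Leiden resolution 0.5. Each cluster was named after the marker list with the highest mean log2(TPM + 1) in it, at least 3 of whose genes had to be above 0 in 25% of its cells; the lists were fixed before the data were examined. Of the symbols in the lists, 2 were found under an older name (Chil3 as Chi3l3, Hbb-bs as Beta-s) and Hbb-bt, Ighm and Ly6g were not matched. The splits among neutrophil-like clusters changed with the settings and with the order of the cells, so these clusters are used for description only.

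The planned comparisons were to be made in microglia-like cells. No cluster met that name, and the comparisons were made in the neutrophil-like cells instead, a choice made after seeing the data. For the inflammatory and the disease-associated list, a score per cell was the mean z-score of log2(TPM + 1) over list genes above 0 in at least 5% of cells, taken as the residual on log10 genes detected within each plate. Cells were ranked by score within each plate and divided into 3 classes of equal size. TPM was averaged over the highest and over the lowest class in each replicate. The 4 averages, as log2(mean TPM + 1), were compared with limma 3.58.1 (R 4.3.3; trend and robust options) with the replicate as a block and Benjamini-Hochberg adjustment at 0.05. Genes with a mean TPM of at least 5 and values above 0 in at least 10% of cells were tested, without the genes of the score list. Fold changes on the log2(mean TPM + 1) scale understate the change of genes with low values. The fit has 1 residual degree of freedom and leans on the variance prior that limma takes from all genes. In the inflammatory fit this prior was infinite. Its SE and p values thus reflect the variance typical of genes at that level, and not a gene's own spread between replicates. Fixed gene lists were tested with camera at a preset correlation of 0.01, and with an estimated correlation beside it. The estimated form rests on the 1 residual degree of freedom and can hardly pass any list. For antigen presentation on the inflammatory score the estimated correlation was -0.2, yet the unadjusted camera p rose from 0.00877 to 0.228. A list that fails the estimated form is therefore not shown to fail because its genes are correlated, and that question stays open. Spearman correlations between list scores were computed across cells within each plate, without p-values. Replicates were compared by size alone: a log2 difference of at least 1 with both plates of one replicate above both of the other, against the same count for the other pairings of the 4 plates.

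Named genes on each score were the 12 largest rises and the 12 largest falls among genes with an adjusted p under 0.05 and the same sign in all 4 plates, apart from predicted genes and pseudogenes. Where fewer passed, all were named, and where none passed, the 5 each way with the smallest p. For replicate differences the 8 largest each way by the size rule were taken, and from each fixed list members with large and small values. Lists of specific granule genes (Camp, Ngp, Ltf, Lcn2, Chi3l3, Cd177, Itgb2l and Mmp8) and azurophil granule genes (Mpo, Elane, Prtn3 and Ctsg) were added after seeing the data.

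The fit was tested on simulated data in which each gene's values were shuffled among cells within a plate, and 200 genes were changed in random classes, in 20 sets per score. For the inflammatory score (4038 genes), 39% of genes raised 4-fold, 6.9% of genes raised 2-fold, 3.9% of genes lowered 2-fold and 12.8% of genes lowered 4-fold were found, and 8.61% of 685 calls were false. For the disease-associated score (4041 genes) the shares were 42.7%, 8.8%, 5% and 13.9%, and 17.8% of 856 calls were false. The false share is thus above the 5% that the adjustment sets. Each gene was shuffled on its own, which removes the correlation between genes, and each change was the same in both replicates. These shares therefore need not hold for the real fit. In simulated sets where limma set an infinite prior (1 set for the inflammatory score, 4 for the disease-associated score), 24.2% and 26.9% of calls were false. The real inflammatory fit also has an infinite prior. As a further check, 100 random lists matched on mean expression were scored and tested in the same way. Alternatives covered the pseudocount (0.1 and 10), no filter on low values, averages of log values, the score without adjustment for genes detected or also adjusted for immediate early genes, 4 or 2 classes, at least 1000 genes per cell, all cells, no replicate block, averages per plate, leaving out each replicate, other cluster settings and other detection thresholds.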

Results

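RNA was measured in 326 individual Optn knockout cells sorted from mouse spinal cord, 154 in replicate 1 (77 each on plates 1 and 2) and 172 in replicate 2 (85 on plate 3 and 87 on plate 4). A median of 1681 genes per cell had TPM above 0, with a range of 675 to 5707. The median was 1761.5 in replicate 1 and 1565 in replicate 2. Rn45s, the ribosomal RNA precursor, took a median of 3.67% of TPM per cell and at least 10% in 7 cells.

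Optn, the targeted gene, was listed at 0 in all 154 cells of replicate 1 and all 172 cells of replicate 2, which allows shares of up to 1.95% and 1.74% of cells with a value above 0. Optn lies on chromosome 2 from 5020642 to 5064051 on the minus strand (GRCm38, the assembly also called mm10, GENCODE annotation; gene ENSMUSG00000026672.11). With no cells of another genotype analysed here and 9283 genes at 0 in every cell, the value is given as a description of the labels' genotype and not as a comparison. Of the sex-linked genes, Ddx3y (Y-linked) was above 0 in 27.9% of cells of replicate 1 and 23.8% of replicate 2, and the mean TPM of Xist was 0.00963 ± 0.00241 (SD, n = 2).

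The first question was which cells the sort had collected. Most cells had the transcripts of neutrophils, the short-lived granulocytes made in bone marrow. The 3 most abundant transcripts on average were S100a9 (71216 TPM), S100a8 (54942 TPM) and Rn45s (40048 TPM), followed by Ngp (32650 TPM), Lyz2 (28465 TPM) and Retnlg (18822 TPM). S100a8 and S100a9 form calprotectin, the main cytosolic protein of neutrophils, and Ngp is a granule protein. Neutrophil-like clusters held 290 of the 326 cells: 87.0% of cells in replicate 1 (95% interval 80.7% to 91.9%) and 90.7% in replicate 2 (85.3% to 94.6%), a mean of 88.9% ± 2.61 (SD, n = 2). The other 36 cells formed a monocyte-like cluster, with 20 of the 154 cells of replicate 1 (95% interval 8.12% to 19.3%) and 16 of the 172 cells of replicate 2 (5.41% to 14.7%).

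No cluster had the microglia list as its highest. The monocyte-like cluster also had enough microglia and neutrophil markers for those names, and took its own from the higher mean log2(TPM + 1) of the monocyte list (5.91, against 1.83 for neutrophil and 1.51 for microglia genes). P2ry12 and Tmem119, genes restricted to microglia within the brain and spinal cord, were above 0 in 2 and 3 of the 326 cells, and the microglial transcription factor Sall1 in 0, which allows a share of up to 0.920%. The complement genes C1qa, C1qb and C1qc, among the most abundant transcripts of microglia, were above 0 in 1, 1 and 0 cells. Of 13 microglia genes (these 6 with Trem2, P2ry13, Gpr34, Siglech, Fcrls, Olfml3 and Slc2a5), no cell had 3 or more above 0 and the most in any cell was 2. Among the gate genes, Ptprc (CD45) was above 0 in 97.2% of cells and Itgam (CD11b) in 89.6%. Cx3cr1, the third stain, was above 0 in 14.3% of cells of replicate 1 and 9.88% of replicate 2, and in 6.90% of the neutrophil-like cells, at a mean of 0.103 TPM over the replicates. In the monocyte-like cells Cx3cr1 was above 0 in 19 of 36 cells, at a mean of 135 TPM. Transcript levels do not give the stain of a cell.

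**Figure D1:**
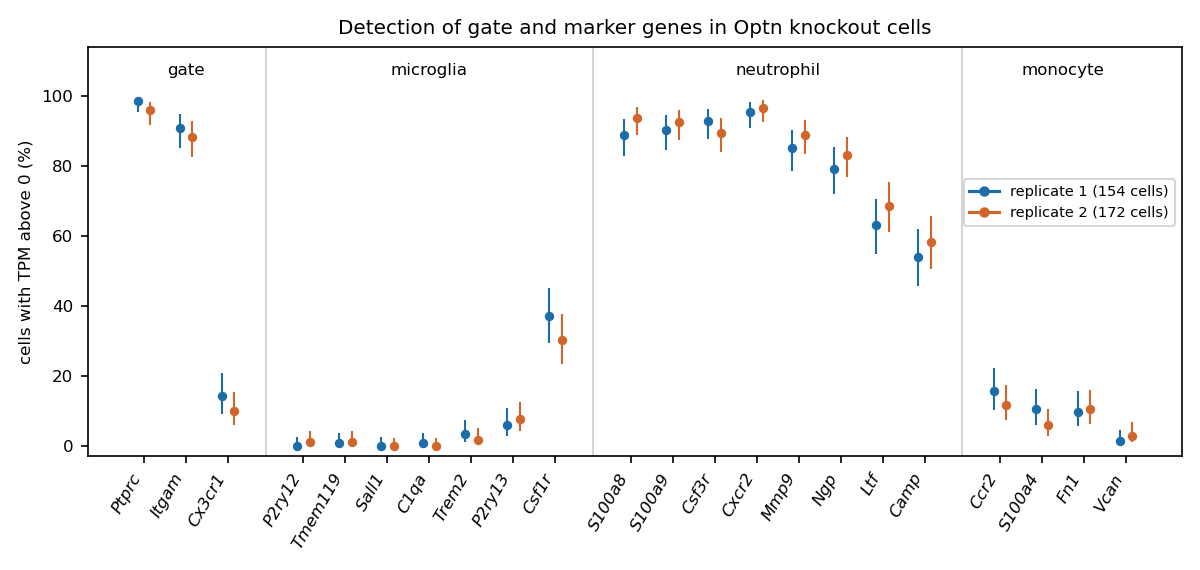
The plot gives the share of cells (%) with TPM above 0 for gate genes and for microglia, neutrophil and monocyte markers. Points are the 2 replicates (154 and 172 cells) and bars are exact 95% binomial intervals. P2ry12, Tmem119 and Sall1 lie near 0 in both replicates, while S100a8, S100a9, Csf3r and Cxcr2 lie near the top.

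The neutrophil-like cells had 9 of the 10 neutrophil markers above 0 in the median cell, and all 290 had at least 5. S100a8 was above 0 in 99.3% ± 1.06 of these cells, Cxcr2 (the neutrophil chemokine receptor) in 97.3% ± 0.683 and Csf3r (the receptor for granulocyte colony-stimulating factor) in 93.5% ± 1.75 (SD, n = 2). Their neutrophil markers summed to a mean of 237985 TPM, against 2304 TPM in the monocyte-like cells. The monocyte-like cells had Ccr2 above 0 in 77.8% and S100a4 in 72.2% of cells, and Ly6c2 at a mean of 5190 TPM. Ccr2 and Ly6c2 mark classical monocytes. Cells with 3 or more markers above 0 numbered 4 for B cells, 3 for T or NK cells, 2 for border macrophages and 1 for oligodendrocytes, all in the monocyte-like cluster, and 0 for astrocytes, neurons, endothelial or mural cells and erythroid cells. Of the neutrophil-like cells, 186 also had 3 or more of the monocyte markers above 0, and the reason was not tested.

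The neutrophil-like cells fell into 5 clusters that differed most in granule genes. The specific granule genes, made in bone marrow while the granules form, had a mean log2(TPM + 1) of 13.16 ± 0.06 (SD, n = 2) in cluster 2 (83 cells) and 2.74 ± 0.31 in cluster 3 (71 cells), with cluster 1 (85 cells) between them at 7.54 ± 0.32. Ltf (lactoferrin) averaged 28561 TPM in cluster 2 and 3901 TPM elsewhere. Cluster 3 was led instead by Egr1 (1197 TPM against 31.4 TPM elsewhere), Fgl2, Tgif1, Prr5l and Cass4, and had the highest immediate early mean of the neutrophil-like clusters, 4.75 ± 0.09. Cluster 6 (25 cells) had Prtn3 and Fcnb, made by early neutrophil precursors, among its leading genes, at means of 1574 TPM and 2028 TPM. Fcnb was above 0 in 96% of its cells, but Prtn3, Elane, Mpo or Ctsg in only 28%, so the Prtn3 mean comes from a minority of them. Its cells had a median of 10 of 16 proliferation genes above 0 against 1 in the other neutrophil-like cells, and Mki67 was above 0 in 72% against 7.17%. This cluster held 9.74% of the cells of replicate 1 and 5.81% of replicate 2. Cluster 5 (26 cells) had specific granule genes at 11.07 ± 0.56, and 5 of the 7 cells with at least 10% of TPM on Rn45s. Cluster borders follow these same genes, so the differences describe the clusters and were not tested.

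**Figure D2:**
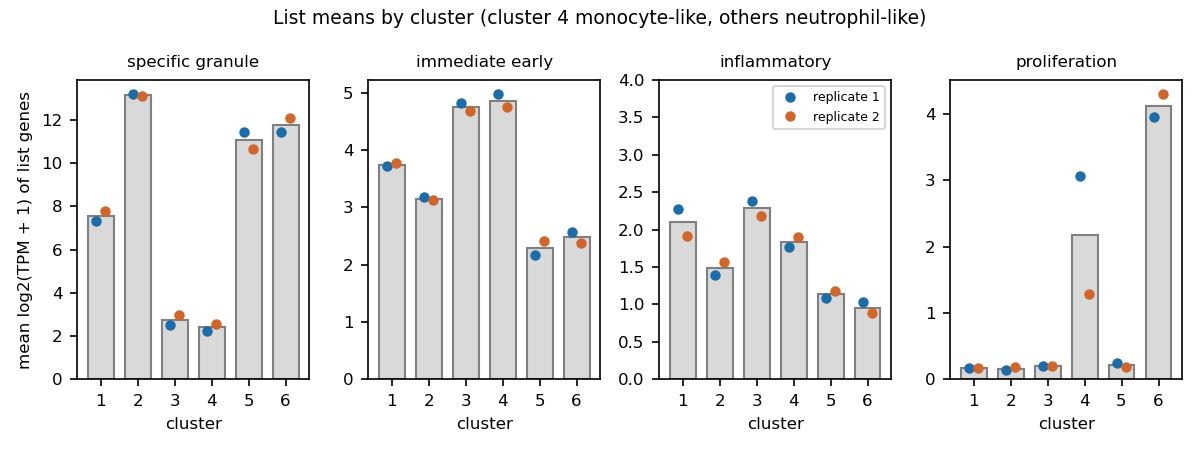
Bars give the mean over 2 replicates, and points the replicates, of mean log2(TPM + 1) over the genes of 4 lists in each cluster. Cluster 4 is monocyte-like and the others are neutrophil-like. Specific granule genes are highest in cluster 2 (13.16), and immediate early genes among neutrophil-like clusters are highest in cluster 3 (4.75). Proliferation genes are highest in cluster 6 (4.13).

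Among the neutrophil-like cells, many transcribed inflammatory genes. Il1b, the precursor of interleukin-1 beta, was above 0 in 59.7% ± 0.0609 of cells at a mean of 6921 ± 561 TPM, and Cxcl2, a neutrophil-attracting chemokine, in 45.9% ± 7.85 at 1083 ± 424 TPM (SD, n = 2). Nfkbia, the NF-kB inhibitor that NF-kB itself induces, was above 0 in 68.7% ± 1.03 of cells and Tnf in 23.3% ± 2.98. Il6, Il1a, Ccl2, Ccl7 and Ccl12 were listed at 0 in all 290 cells. Of the disease-associated list, taken from microglia in degenerating tissue, the genes that neutrophils also use were frequent: Lyz2 in 98.6% ± 1.13, Fth1 in 97.7% ± 2.19 and Cd9 in 87.7% ± 1.60 of cells. Spp1 was above 0 in 6.62% ± 1.20 of cells and Apoe in 2.51% ± 1.73, and Gpnmb and Igf1 were listed at 0 in all cells. Of the interferon-induced list, Ifitm3 was above 0 in 83.5% ± 1.16 and Slfn2 in 83.5% ± 0.176 of cells, and Isg15 in 8.80% ± 3.38 and Ifit1 in 1.07% ± 0.602. Of the homeostatic list, Selplg was above 0 in 84.5% ± 0.203 and Csf1r in 27.5% ± 4.41 of cells, and P2ry12 in 0.641% ± 0.907.

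Of 4038 genes tested, 73 were higher and 15 lower in the 96 cells with a high inflammatory score than in the 96 with a low one (limma, adjusted p under 0.05), and 64 of these 88 had the same sign in all 4 plates. Gadd45b, a stress-induced gene that NF-kB also induces, rose the most of the named genes in this fit. It rose by 5.47 on the log2 scale (limma, SE 0.46, adjusted p = 3.95e-28), from 13.6 to 864 TPM in replicate 1 and from 19.1 to 663 TPM in replicate 2. Nlrp3, the sensor of the inflammasome that processes interleukin-1 beta, rose by 3.67 (limma, SE 0.52, adjusted p = 9.92e-10), and Ccrl2, a chemerin-binding receptor, by 2.84 (SE 0.31). The plates gave Ccrl2 folds from 0.45 to 10.2, a spread that its SE does not measure. Transcription factor genes among the named rises were Jun (3.89), Tgif1 (2.86) and Atf3 (2.44). The other named rises, with log2 folds from 4.55 to 2.38, were Bcl2a1b, Ap4b1, Lrwd1, Sesn2, Sirpb1a and Ogfr. Bcl2a1b and Sirpb1a have near-identical paralogs and their values are uncertain. The first rank of Gadd45b depended on the setting. Ap4b1 had a larger fold with a pseudocount of 0.1, and Ccrl2 with averages of log values and with 4 classes. Bcl2a1b had a larger one with 2 classes, without replicate 1, and with adjustment for immediate early or for specific granule genes. Elsewhere Gadd45b kept the largest fold of the named genes. Ap4b1 was listed at 0 in the low cells of replicate 2 and Sugp1 in the high cells of replicate 2, so their fitted folds depend on the pseudocount. With 1 replicate left out and the score rebuilt, the smaller fold of the pair was 0.98 for Sesn2 (2.73 with both replicates), 2.65 for Bcl2a1b, 1.78 for Ccrl2, 1.80 for Atf3 and 2.17 for Sirpb1a, and Ap4b1, which had a fold in replicate 1 alone, 1.54. The score genes themselves were left out of the test.

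All 9 named falls are these: Stip1 (-4.15), Sugp1 (-3.56), Spint2 (-2.14), Ifitm6 (-0.79), Camp (-0.73), Ngp (-0.61), Ltf (-0.56), S100a8 (-0.53) and S100a9 (-0.47). This order changed with averages of log values. Ngp, Camp, Ltf and Ifitm6 then had the largest falls, each larger than above, and kept their calls. Stip1, Sugp1 and Spint2 had smaller falls and lost their calls, and S100a8 and S100a9 had larger falls without a call. A pseudocount of 10 also made the falls of Stip1, Sugp1 and Spint2 smaller. With 1 replicate left out, the smaller change of the pair was -0.78 for Spint2, -1.46 for Sugp1 and -0.29 for Ltf. Camp, the cathelicidin of specific granules, averaged 18858 TPM in low cells and 12584 TPM in high cells of replicate 1, and 19978 and 10955 TPM in replicate 2. Of the 8 specific granule genes, a list added after seeing the data, 4 fell and 0 rose (camera, unadjusted p = 7.36e-16, and 0.0757 with an estimated correlation); with the score also adjusted for these genes, an alternative added after seeing the data, the log2 fold of Ltf was 0.0241, while Camp, S100a8 and S100a9 were still lower and kept their calls and Ngp was lower without one. Cluster 1 gave 30 of the high cells and 18 of the low cells, cluster 2 gave 24 and 32, cluster 3 gave 31 and 17, cluster 5, which held 5 of the 7 cells rich in Rn45s, gave 6 and 17, and the cycling cluster 6 gave 5 and 12. The score is a range and not a cell type: 48 cells lay within 0.25 SD of the upper class border and 73 within 0.25 SD of the lower one. The count of genes is unstable: it was 0 without the filter on low values, and 1 (Gadd45b) without the replicate block or with at least 1000 genes per cell. It was 0 when the score was also adjusted for immediate early genes, where 201 genes had an unadjusted p under 0.05 in limma and Gadd45b had a log2 fold of 3.67.

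**Figure D3:**
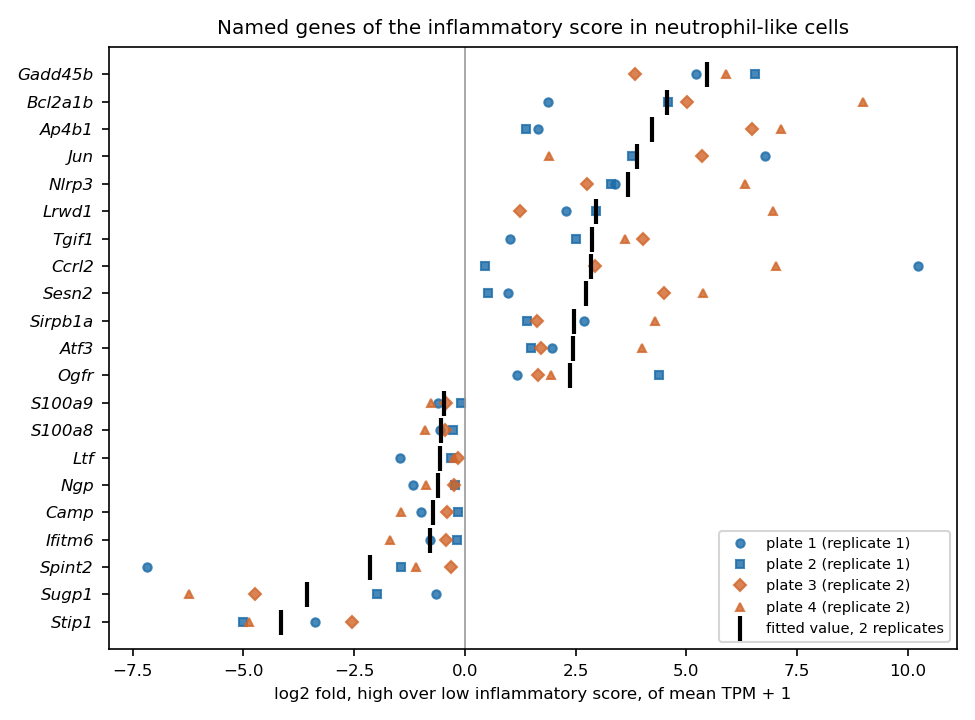
Each row is a named gene and the horizontal axis is the log2 fold of mean TPM + 1 between cells of high and low inflammatory score. Symbols are the 4 plates and black bars the fitted value over 2 replicates. Gadd45b (5.47) leads the rises, and the granule genes Camp (-0.73), Ngp (-0.61) and Ltf (-0.56) are below 0 in every plate.

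Of the 18 tested genes of the immediate early list, 11 rose and 0 fell over all genes tested, and 12 rose adjusted over the list alone, with a median log2 fold of 1.11, 0.472 in replicate 1 and 1.84 in replicate 2 (camera, adjusted p = 2.68e-31; adjusted p = 0.724 with an estimated correlation). The estimated form can hardly pass any list at 1 residual degree of freedom. Beside Jun and Atf3, Egr1 rose by 2.23, Zfp36, whose protein degrades cytokine mRNA, by 2.02, Ier3 by 1.66 and Junb by 1.03, while Hsp90aa1 had 0.80 and Dnajb1 0.11 without passing. Of the genes called, Egr1, Dusp1, Btg2 and Nr4a1 did not have the same sign in all plates. In plate 2 their log2 folds were -0.38, -0.05, -0.19 and -0.84, and those of Fos (0.02) and Junb (0.06) were near 0. Of the 5 tested antigen presentation genes, B2m rose (0.66), and 3 rose adjusted over the list alone (camera, adjusted p = 0.0482; adjusted p = 0.724 with an estimated correlation). This call ended in 6 of the alternatives: no filter on low values, averages of log values, at least 1000 genes per cell, averages per plate, and adjustment for immediate early or for specific granule genes. Of the 11 disease-associated genes tested, Fth1 rose (1.01) and the list did not pass (adjusted p = 0.900). No other fixed list passed: adjusted p was 0.0759 for oxidative phosphorylation, 0.196 for the homeostatic list (Selplg rose by 0.87), 0.209 for cell death and RIPK1 (Nlrp3 rose) and 0.486 for autophagy and lysosome (Tfeb rose by 1.98). It was 0.900 each for interferon, proliferation and lipid and cholesterol, and 0.917 for glycolysis and hypoxia. Proliferation passed with the score not adjusted for genes detected, with 2 classes, with all cells and with adjustment for specific granule genes, and oxidative phosphorylation with averages of log values, the unadjusted score and 2 classes. With all cells the homeostatic, the cell death and RIPK1 and the autophagy and lysosome lists passed too.

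For the disease-associated score, 0 of 4041 genes passed (limma; 351 genes had an unadjusted p under 0.05, and the smallest adjusted p was 0.0573). The genes with the smallest p that were higher in high cells were Retnlg (0.99), Fpr1 (1.29), Cdc42ep2 (2.72), Rfc2 (2.52) and Mgst1 (1.01). Those lower were Ube2c (-6.09), Hist1h2ao (-3.64), Tuba1b (-3.24), Ppia (-2.00) and Chi3l3 (-1.30). None of these 10 passes in this fit, though over the alternatives their folds gained a call in 60 cases. The log2 fold of Hist1h2ao was 0.56 when the cycling cluster was left out, an alternative added after seeing the data. Ube2c encodes a ubiquitin-conjugating enzyme of the cell cycle. It averaged 177 TPM in low cells and 0.982 TPM in high cells of replicate 1, and 94.1 and 0.841 TPM in replicate 2. Cluster 1 gave 46 of the high cells and 8 of the low cells, cluster 2 gave 21 and 24, cluster 3 gave 22 and 33, cluster 5 gave 5 and 17, and the cycling cluster 6 gave 2 and 14. Cdc42ep2 is also among the leading genes of cluster 1 (270 against 69.0 TPM elsewhere). The proliferation list was lower as a set (4 genes, median log2 fold -4.00; camera, adjusted p = 1.35e-06; adjusted p = 0.739 with an estimated correlation), as were oxidative phosphorylation (20 genes, median -0.67; adjusted p = 0.00663, and 0.739 with an estimated correlation) and immediate early genes (18 genes, median -0.30; adjusted p = 0.00207, and 0.739 with an estimated correlation). As on the other score, the estimated form can hardly pass any list. Adjusted over the list alone, 4 proliferation and 3 immediate early genes fell. The 8 specific granule genes, the list added after seeing the data, were lower on this score too (median log2 fold -0.52, camera, unadjusted p = 0.000892, and 0.438 with an estimated correlation). Over that list alone 4 fell and 1 rose. The direction of the immediate early list turned when log values were averaged (adjusted p = 0.240). The inflammatory (adjusted p = 0.488), homeostatic (0.867), interferon (0.364), antigen presentation (0.9996), cell death and RIPK1 (0.762), autophagy and lysosome (0.331), glycolysis and hypoxia (0.364) and lipid and cholesterol (0.867) lists did not pass. The count of genes was 143 when log values were averaged.

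Across neutrophil-like cells within a plate, the inflammatory score went with the immediate early score, with Spearman rho of 0.39, 0.39, 0.53 and 0.59 in plates 1 to 4. It also went with the antigen presentation score (0.20, 0.21, 0.20 and 0.26). The specific granule score ran against the immediate early score in every plate (-0.52, -0.50, -0.48 and -0.54) and against the inflammatory score (-0.39, -0.17, -0.31 and -0.25). It also ran against the proliferation score (-0.47, -0.60, -0.29 and -0.28). The cycling cluster 6 was not low in specific granule genes. Their mean log2(TPM + 1) there was 11.77, below cluster 2 (13.16) and above clusters 5 (11.07), 1 (7.54) and 3 (2.74). This rho therefore does not show that cycling cells have few granule transcripts. The inflammatory and the disease-associated scores were close to unrelated (-0.005, 0.08, 0.12 and 0.04), and interferon genes had no common sign with the inflammatory score (0.27, -0.14, -0.02 and 0.11). Of the 11 pairs computed, the lists of each pair share no gene. Cells of one plate are not replicates, so no p is given.

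By the size rule, 242 of 4052 genes differed between the neutrophil-like cells of the replicates, 105 higher in replicate 1 and 137 higher in replicate 2. The other pairings of the 4 plates gave 255 and 221 genes. Bcl2a1d, one of several near-identical paralogs, had the second largest excess in replicate 1 (87.1 against 7.93 TPM) after Nol11 (10.7 against 0.163 TPM), and Tor2a, Rad51d, Cass4, Ppm1a, Sema4b and Bloc1s2a followed. The largest excess in replicate 2 was that of Zfp617 (16.6 against 0.644 TPM), before Endov, Zfp866, Abcd4, Gpr35, Itpripl1, Atpaf2 and Mfn2. Mean TPM of the replicates correlated across genes with Pearson r of 0.957 on the log2 scale; genes are not independent replicates. With log values averaged, 99 genes passed, of which 98 were higher in replicate 1, against 30 and 28 in the other pairings. Averages of log values depend on how many cells are above 0. Over all cells, replicate 1 had a median of 1761.5 genes above 0 and replicate 2 had 1565. An effect of detection was not told apart from a difference in level here. The replicates also gave the highest of the 3 counts with a pseudocount of 10 (79 against 66 and 64) and without the filter on low values (1469 against 1415 and 1422), but not with at least 1000 genes per cell (229 against 242 and 214).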

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

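The tests of the missing microglia were chosen only after the result was seen. The comparisons of the report used the neutrophil-like cells, and signal in the cells outside them stood above the limit that a count of 0 allows. The monocyte-like cluster held 36 cells. Within it, 4 cells had 3 or more B cell markers above 0, and 2 cells had both Nkg7 and Klrb1c, which natural killer cells use.

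No microglia-like cells were found in a series titled as microglia. The tables argue against low depth, since 92.3% of cells had at least 5 of 10 neutrophil markers above 0 and a loss of reads adds no transcripts of another cell type. Neutrophil RNA mixed into wells that held microglia would leave the microglia's own transcripts in place, and the 13 microglia-restricted genes summed to a mean of 54.9 TPM in neutrophil-like cells. That other CD45 and CD11b bearing myeloid cells were sorted into the wells remains a candidate explanation: Itgam was above 0 in 90.3% of neutrophil-like cells and Cx3cr1 in 6.90%, although the stain and the gate of each cell were not analysed here. Whether the sorted cells lay in the spinal cord itself or came with it from elsewhere in the animal was not tested. Among them were cycling cells with a precursor gene (cluster 6, with Mki67 above 0 in 72% and Fcnb in 96% of cells). A mix-up of plates or tables was not tested, and since all cells share 1 genotype label no biological explanation was tested.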

How the results depend on the processing

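The alternatives named here as added were chosen after seeing the data: the adjustment for specific granule genes, leaving out the cycling cluster, removing Rn45s, and leaving out cells rich in Rn45s. Cell type shares kept their values within 1 SD under every alternative run, and 0 cells changed between neutrophil-like and monocyte-like. The 88 genes of the inflammatory score became 56 with a pseudocount of 0.1, 50 with 2 classes, 41 with all cells, 4 with averages per plate, 1 with at least 1000 genes per cell, 1 with no replicate block, 0 with no filter on low values and 0 with adjustment for immediate early genes. With the added alternatives they became 25 with adjustment for specific granule genes, 43 without the cycling cluster and 50 without Rn45s. The 4 genes per plate were Gadd45b, Nfkbid, Zfp36 and Clec4d. The 0 genes of the disease-associated score became 3 with a pseudocount of 10, 143 with averages of log values, 4 with the unadjusted score, 11 with 4 classes, 30 with 2 classes, 5 with at least 1000 genes per cell, 8 with all cells, 4 with no replicate block and 39 with adjustment for immediate early genes, and with the added alternatives 50 (specific granule genes), 10 (no cycling cluster) and 22 (no Rn45s). The limma prior moved with these settings. The rise of the immediate early list had an adjusted p of 0.0509 once its own score was removed, and its fall on the disease-associated score turned to a rise with averages of log values (adjusted p = 0.240). The log2 fold of Ltf turned to 0.0241 with adjustment for specific granule genes and that of Hist1h2ao to 0.56 without the cycling cluster. Of the replicate differences, 79 passed with a pseudocount of 10 (66 and 64 in the other pairings of plates), 99 with averages of log values (30 and 28), 1469 without the filter (1415 and 1422) and 229 with at least 1000 genes per cell (242 and 214). Apart from those stated, the cause was not tested. Leaving out a replicate leaves no residual degrees of freedom, so only folds and correlations were computed; the rho of the inflammatory and immediate early scores lay between 0.39 and 0.56. For named genes, 162 calls were lost on the inflammatory score and 199 cases did not change. On the disease-associated score 60 calls were gained and 112 cases did not change. An unchanged case had the same call status or, with a replicate left out and no test, a fold within 1 SD. A kept call is not a kept fold. With averages of log values the folds of Ngp, Camp, Ltf and Ifitm6 grew and that of Jun shrank, with all these calls kept. With 4 classes the fold of Ccrl2 grew. Without the filter on low values or the replicate block the folds kept their main values while calls were lost. With a replicate left out 6 folds moved by more than 1 SD on each score. On the inflammatory score the folds of Sesn2, Bcl2a1b, Ap4b1, Ccrl2, Atf3, Sirpb1a, Spint2, Sugp1 and Ltf then changed by over 1.5 times. Of the list tests, 14 lost a call and 14 gained one. The losses on the inflammatory score were 6 of antigen presentation and 1 of immediate early genes. Those on the disease-associated score were 4 of oxidative phosphorylation and 3 of immediate early genes. The gains included 4 of proliferation and 3 of oxidative phosphorylation on the inflammatory score. Of the list score correlations 16 moved by more than 1 SD and 28 did not. Of the shares of state genes 16 did and 104 did not. The Optn share is 0 in every cell and could not move, and the mitochondrial filter had no genes to act on, so neither is a test. At this depth a share of 0 limits only cells with a value above 0.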

Other observations

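The tests of the granule pattern were set before their results were seen, and those of the inflammatory pattern after; the adjustment for immediate early genes was itself fixed before the values were seen, but what it should show was written after. The monocyte-like cells had a profile of their own. Csf1r, the receptor for colony-stimulating factor 1, was above 0 in 83.8% ± 5.30 of these cells (SD, n = 2). F13a1 was above 0 in 78.1% ± 4.42 and averaged 1088 ± 147 TPM, and Plac8 averaged 2377 ± 327 TPM. Apoe averaged 2815 ± 2314 TPM and was above 0 in 53.1% ± 4.42 of cells, against 2.51% ± 1.73 of neutrophil-like cells. Trem2 was above 0 in 8 of the 36 cells and Aif1 in 12, and both were listed at 0 in all neutrophil-like cells. Azurophil granule genes (Mpo, Elane, Prtn3 or Ctsg) were above 0 in 28% of the cycling cluster and 0.377% of the other neutrophil-like cells. They were not particular to the cycling cluster. Their mean log2(TPM + 1) was 1.03 ± 0.56 in the monocyte-like cluster and 1.23 ± 0.88 in the cycling cluster (SD, n = 2). In the remaining clusters it was 0.015 or less.

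Immediate early genes were high where specific granule genes were low. Granule genes take much of the TPM total (a group of 12 granule and other abundant genes held 38.9% in cluster 2 and 10.8% in cluster 3), which lowers all other genes. With these 12 genes removed and the rest rescaled, rho averaged -0.47 over the plates, against -0.51 before. Among the middle 50% of cells by genes detected rho averaged -0.51, and without the cycling cluster -0.54, with each plate below -0.25 in all 3 tests. The rescaling and the run without the cycling cluster argue against scaling by the TPM total and against cycling cells as the whole cause. The scores were already residuals on log10 genes detected. Restricting the cells by genes detected could thus change rho little, and that test does not decide on the number of genes detected. The rescaling leaves values of 0 at 0, so it cannot restore immediate early transcripts missed where granule RNA took the reads. That part stays open. Whether the pattern arises in the tissue or during digestion stays open, since no undigested cells were analysed here.

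Inflammatory and immediate early genes rose together. Of 100 random lists of genes as abundant, 2 called as many genes as the 88 of the inflammatory list (median 12, highest 109), so few such lists do. The inflammatory fit had an infinite limma prior, and the priors of the random fits were not set beside it. A difference in prior can change the count. The comparison therefore does not show that the inflammatory list is unlike other genes as abundant. For the disease-associated list, which called 0, the random lists called a median of 22 genes and at most 336. With the score also adjusted for specific granule genes the immediate early list had a median log2 fold of 0.79 (1.11 before), 0.225 in replicate 1 (0.472 before) and 1.48 in replicate 2 (1.84 before). The members called fell from 11 to 3 of 18, with smaller folds and a limma prior of 20.1 degrees of freedom in place of an infinite one. At an estimated correlation the list passed neither before nor after (camera, adjusted p = 0.724 each). With 1 residual degree of freedom that form can hardly pass any list, so it does not bear on maturation. The replicates were unlike both before the adjustment (SD 0.967, n = 2) and after it (SD 0.887), so this spread does not bear on maturation. Replicate 1 lost a larger share of its fold than replicate 2. The adjustment therefore does not decide on neutrophil maturation, which stays open. Stress of tissue digestion cannot be told apart from activation in the animal: heat shock members of the list, which digestion may induce, had a median log2 fold of 0.45 with 0 of 3 passing, and no cells prepared another way were analysed here. Adjusting for the immediate early score ended the call of Gadd45b (5.47 with SE 0.46 before, 3.67 with SE 0.36 and adjusted p = 0.0693 after), and this removes shared signal of either origin.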
